A study of Homo sapiens with 6 samples.

How the data were processed

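The 6 deposited value columns were used, one for each hybridisation, 3 on slide part A and 3 on slide part B. Per the labels, total RNA of irradiated HCT116-CloneK (4 Gy, 6 h) and of unirradiated HCT116-Clone10 was labelled with Cy5 or Cy3, with the dyes exchanged on replicate 2, and slides were scanned with ScanArray Express and quantified with QuantArray. Per the labels, the authors deposited log2 ratios per spot, after subtraction of the sub-array background and a regression normalization within each sub-array in the Normaliser2 macro. Per the labels, spots with a signal over background below 2.5, spots under a 5% intensity limit and damaged spots were filtered out. The direction of the ratio, the channel intensities and the regression settings are not given in the sources used here, so the signal over background of single spots could not be used. Array medians of the deposited values lay between -0.07 and 0.04 log2 units.

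Spot numbers were named through the platform annotation, whose gene symbols were checked by gene identifier against the RefSeq table of GRCh38.p14. This changed 0 symbols, and 8 spots with a single symbol on each part had no match and kept the symbol listed. A single symbol was found for 7872 of 19200 spots on part A (41.0%) and 8000 of 19200 on part B (41.7%), several symbols for 346 and 312, and none was listed for 10982 and 10888, which were used without a name. The build of the array's design is not given in the sources used here, so no coordinates are printed. Neighbouring spots shared their clone in 4109 of 4109 listed pairs on part A and 4156 of 4156 on part B. The layout of 32 sub-arrays of 25 rows and 24 columns, 4 side by side, was inferred from the correlation of values along the spot order and was used to remove local trends.

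Spots of one clone were averaged, then clones of one gene symbol. Unnamed spots stayed single features. Features with a value on all 3 arrays were tested, 13457 on part A and 12913 on part B. Each part was fitted alone, since the parts hold different clones and were normalized separately. The test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) of the mean log2 ratio against 0, two-sided, with Benjamini-Hochberg adjustment within the part and a threshold of 0.05. The design planned before the data were examined used all 3 arrays, with the sign of replicate 2 set by its correlation with the mean of replicates 1 and 3 (kept above 0.1, turned below -0.1, otherwise left out of the main fit). The last case applied on both parts. Each fit therefore held 2 arrays of the same dye assignment, and the rules written for all 3 arrays (genes at least 1.5-fold apart, and named genes) were evaluated on replicates 1 and 3, with both signs of replicate 2 beside the counts by size.

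Named genes followed a fixed rule. Per part and direction it took the 6 genes with the largest mean among those past the threshold and, because none passed, among those with an unadjusted p under 0.01 and the same sign on the fitted arrays; only 2 genes met this for higher values on part B. It also took 17 fixed genes of the radiation response wherever measured, and up to 4 members of each of 24 gene lists in order of the absolute moderated statistic over both parts, of which the text names the first 2. The number 2 was set after the values and sign changes were seen, to keep the text short. Lists were tested with limma's cameraPR (preset inter-gene correlation 0.01, at least 4 measured genes, two-sided, Benjamini-Hochberg over the lists of both parts). Adjusted p-values are printed singly for the 3 lists that had an unadjusted p under 0.05 on a part, on both parts, a choice made after the values were seen. The estimated correlation came from limma's formula applied by hand to 1 residual degree of freedom per gene, limited to between 0 and 0.99, because limma's own function could not be fitted with 2 arrays. The difference between the parts was tested for the shared genes with limma, 2 arrays against 2, a test added after the results were seen. Correlations across genes were tested with 100000 permutations, two-sided, and their 95% intervals come from Fisher's transformation (Python 3.11.15, scipy 1.17.1).

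The tests were tried on simulated data with known changes; the simulation of correlations was added after the correlations had been seen. Features drawn from the fitted spread, with 200 changed genes per run and 20 runs, gave the recovery stated with the results (13457 features on part A and 12913 on part B). Simulated gene lists without a shift had an unadjusted p under 0.05 in 4.5% of runs on part A and 3.5% on part B. Simulated correlations of 0.3 were detected in 100% of runs over 520 genes and in 94% of runs over 100 genes, and simulated correlations of 0 had a p under 0.05 in 5% and 4% of runs.

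Alternatives were a dye term, both signs of replicate 2, features on at least 2 arrays, new median centring, scale normalization between arrays, single spots, robust eBayes, adjustment over both parts, other fold thresholds, a rank-based list test, an estimated correlation and leaving out replicates. After seeing the data, removal of a local trend (the mean of a window of 7 by 7 spots without the spot and its duplicate, values limited to 2 log2 units either way), a test of named genes only and an average of unnamed neighbouring spots were added. In all, 16 limma settings per part, 5 of them added in this way, and 15 gene list settings were run. Array weights cannot be estimated from 2 arrays, so limma's arrayWeights was not run.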

Results

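RNA from irradiated HCT116-CloneK cells was hybridised directly against RNA from unirradiated HCT116-Clone10 cells on spotted cDNA microarrays. HCT116 is a human colorectal cancer cell line. CloneK is a clone of it that is sensitive to X-rays, and Clone10 is a clone whose X-ray response is close to that of the parental line. CloneK cells received 4 Gy, and their RNA was collected 6 h later. The probes were divided over 2 slide parts, called A and B, which carry different clones, and each part was hybridised 3 times. Cy5 labelled CloneK on replicates 1 and 3, and Cy3 labelled CloneK on replicate 2, the dye swap. Each part held 19200 spots, and between 2.68% and 6.30% of the spots of an array had no value. A single gene symbol was listed for 7872 spots of part A and 8000 of part B, which represented 3449 and 3361 genes. RNA of several batches had been pooled, so the 3 arrays of a part may be technical repeats. The p-values of single genes or spots below measure only the spread between hybridisations. Those of gene lists and of correlations compare genes or clones with each other and do not measure a spread between cultures. Each array set one irradiated clone against another, unirradiated clone, so a ratio holds the difference between the clones and the response to irradiation together. Each array carried its own labelled Clone10 RNA, so the spread of the ratios holds differences of the control between hybridisations. A spread between cultures of either clone may be missing from it. The number of arrays limits the precision of all values.

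Replicates 1 and 3 resembled each other weakly and replicate 2 resembled neither. Over means of neighbouring spots, the Pearson correlation of replicates 1 and 3 across clones was 0.272 on part A and 0.181 on part B. Replicate 2 gave -0.0361 with replicate 1 and -0.0189 with replicate 3 on part A, and -0.108 and -0.0650 on part B. Clones are not independent replicates, and these correlations describe the arrays only. A rule fixed before the data were examined took the sign of replicate 2 from its correlation over all spots with the mean of replicates 1 and 3. That Pearson correlation was -0.0167 on part A and -0.0829 on part B, between the bounds of -0.1 and 0.1, so replicate 2 entered no main test. The Spearman correlation, which the rule did not use, was -0.0100 on part A and -0.121 on part B. All values below are means over replicates 1 and 3 (n = 2), which share a dye assignment, so dye effects cannot be separated from the difference between the RNAs. The labels do not state the numerator of the ratio. CloneK was both the second channel and the Cy5 channel on these arrays, so positive values likely mean more RNA in irradiated CloneK, and directions below are given on that basis.

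**Figure D1:**
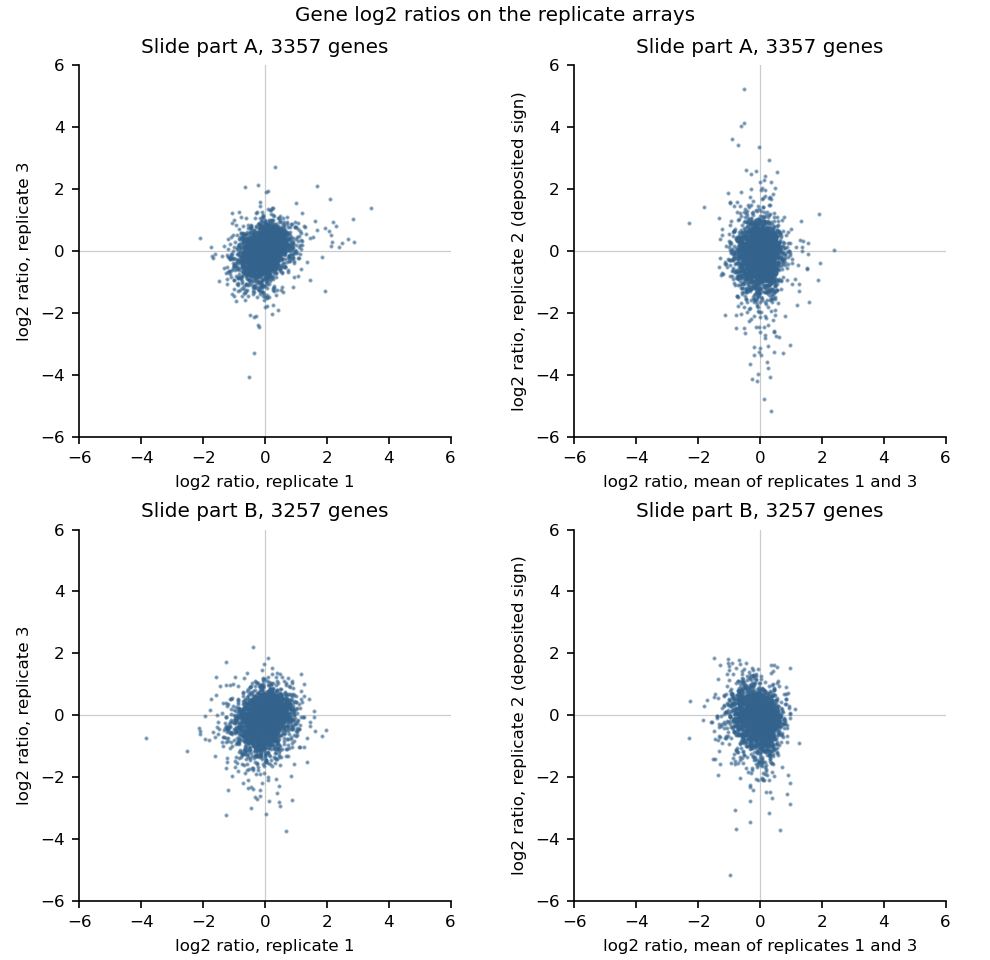
Each point is a gene, placed by its log2 ratio on replicates 1 and 3 (left) or by the mean of replicates 1 and 3 and the deposited value of replicate 2 (right), for the 3357 genes of slide part A and the 3257 genes of slide part B. Points on the left lean weakly along the diagonal, and points on the right show no clear slope.

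Genes of slide part A were ranked by their mean log2 ratio. Only genes with an unadjusted p under 0.01 (limma) and the same sign on replicates 1 and 3 were ranked. Among them the largest means in favour of irradiated CloneK belonged to SLC1A3, a glutamate transporter, at 2.40 ± 1.44 (SD, n = 2), and to ANKS1B, at 1.90 ± 0.29, whose clones on part B gave 0.26. ATL1, a GTPase that shapes the endoplasmic reticulum, followed at 1.88 ± 0.29. ODAPH gave 1.56 ± 0.90, the phosphatase DUSP28 gave 1.29 ± 0.47, and MET, the receptor of hepatocyte growth factor, gave 1.28 ± 0.41. In the other direction stood the transcription factor NFIC at -1.28 ± 0.48, the small GTPase RAB21 at -1.23 ± 0.25, the microtubule end-binding protein MAPRE3 at -1.23 ± 0.37, the cyclin-dependent kinase CDK14 at -1.22 ± 0.32, LRATD2 at -1.14 ± 0.12, against 0.03 on part B, and the homeobox gene OTX2 at -1.12 ± 0.17. All 12 had an unadjusted p below 0.01 and the same sign on replicates 1 and 3, and each had an adjusted p of 0.477, so none of them passed the test. On replicate 2, 8 of the 12 had the same sign as deposited and 4 the opposite sign. CDKN1A, the p21 cell cycle inhibitor that p53 induces, had a mean log2 ratio of 0.31 ± 0.13 (adjusted p = 0.589, limma), and its sign turned when replicate 2 was added with its sign turned, to -0.02. With a local trend removed from replicates 1 and 3 it was 0.65.

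Across part A, 0 of 13457 features, 3357 of them named genes, passed an adjusted p of 0.05 in limma, against 1348 features at an unadjusted p under 0.05. By size alone, 100 genes were at least 1.5-fold apart in the same direction on replicates 1 and 3, 37 of them higher and 63 lower in CloneK. At the same size 19 genes were apart in opposite directions on these arrays. A single array gave 572 such genes without replicate 1 and 444 without replicate 3. The rule had been written for all 3 arrays, and with replicate 2 it was met by 16 genes with the deposited sign and by 17 with the sign turned. The other sign patterns, in which replicate 1 or 3 opposed the rest, held 4 and 5 genes. After removal of a local trend from each slide, replicates 1 and 3 gave 64 genes, 29 higher and 35 lower.

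Genes of slide part B were ranked under the same limit, an unadjusted p under 0.01 (limma) and the same sign on replicates 1 and 3. Among them the largest mean log2 ratio in favour of irradiated CloneK belonged to MGST3, a microsomal glutathione transferase, at 1.25 ± 0.13 (SD, n = 2), and the next to SLC7A4, of a family of amino acid transporters, at 1.14 ± 0.17. In the other direction, under this limit, RECK came first, an inhibitor of matrix metalloproteinases, at -2.25 ± 1.39. The proteoglycan gene SPOCK1 stood at -1.83 ± 0.97, the zinc transporter SLC39A2 at -1.80 ± 0.87, the histone demethylase KDM2B at -1.52 ± 0.64, LZTFL1 at -1.49 ± 0.32 and VOPP1 at -1.47 ± 0.22. The adjusted p was 0.612 for each of these 8 genes, so none passed. On replicate 2, 4 of the 8 had the same sign as deposited and 4 the opposite sign. CDKN1A gave 0.09 ± 0.22 on this part, with 0.24 on replicate 1 and -0.06 on replicate 3. The damage-response kinase ATM gave -0.18 ± 0.54, with -0.56 on replicate 1 and 0.21 on replicate 3. Of 17 genes of the radiation response fixed in advance, CDKN1A and ATM were the 2 that had a named spot.

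Across part B, 0 of 12913 features, 3257 of them named genes, passed an adjusted p of 0.05 in limma, and 1024 had an unadjusted p under 0.05. By size alone, 116 genes were at least 1.5-fold apart in the same direction on replicates 1 and 3, 25 higher and 91 lower in CloneK, and 45 were apart in opposite directions. A single array gave 685 such genes without replicate 1 and 539 without replicate 3. With replicate 2 the rule was met by 20 genes with the deposited sign and by 25 with the sign turned, and the other sign patterns held 17 genes with replicate 1 and 6 with replicate 3 opposed to the rest. After removal of a local trend, replicates 1 and 3 gave 93 genes, 32 higher and 61 lower. In data simulated with the spread of these arrays and 200 changed genes, the test on 2 arrays recovered 59.4% of 4-fold changes on part A and 17.9% on part B, 96.2% and 93.0% of 8-fold changes, and 0% of 2-fold changes on either part. With 3 simulated arrays of that same spread it recovered 90.7% of 4-fold changes on part A and 83.9% on part B. It again recovered 0% of 2-fold changes on either part. The spread was that of replicates 1 and 3, which replicate 2 did not follow, so this gain may not hold for replicate 2.

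**Figure D2:**
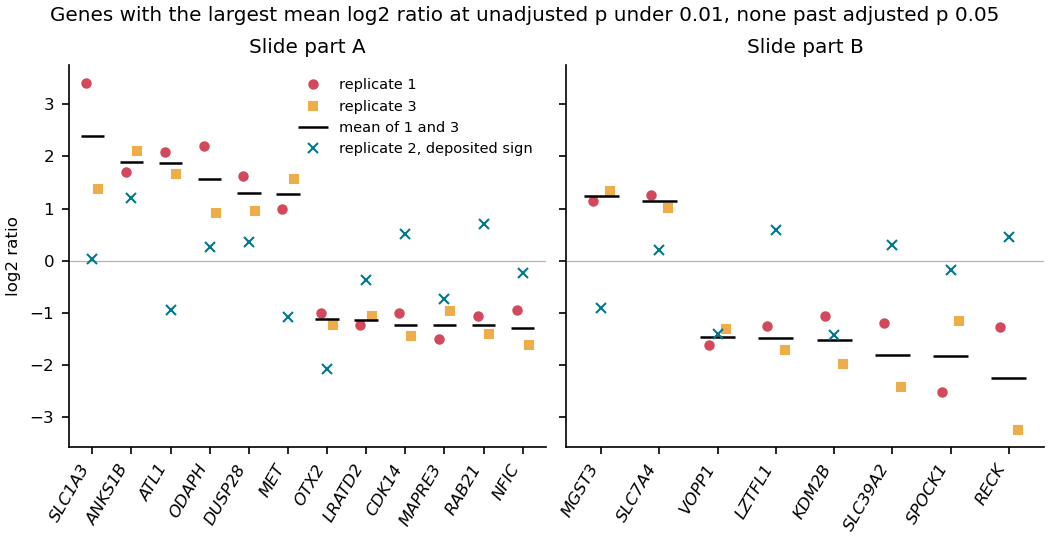
Log2 ratio of the genes with the largest mean at an unadjusted p under 0.01, on slide part A (left) and slide part B (right). Circles are replicate 1, squares replicate 3, black lines their mean, and crosses replicate 2 as deposited, which shares the sign of the mean for 12 of the 20 genes.

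Gene lists fixed in advance were compared with the other genes of their slide part, to ask whether genes of a pathway moved together. Lists with at least 4 measured genes gave 34 tests, 14 on part A and 20 on part B, and 0 of them passed an adjusted p of 0.05 (cameraPR with a preset correlation). Genes of the antioxidant and NRF2 list came closest, on part B, where 5 of 6 measured members had positive log2 ratios, with a median of 0.41 and an adjusted p of 0.0633 (cameraPR of limma). MGST3 was the 1 member of this list that passed when adjusted over the list alone; 0 passed over all features. With an estimated correlation, which 2 arrays give only crudely, the list reached an adjusted p of 0.0487, in a range of 0.0487 to 0.948 over its alternatives. That estimate was 0, the lower limit set for it, so this cameraPR test took the genes of the list as independent. On part A the same list had 3 of 5 members above 0, with superoxide dismutase SOD2 at 0.56 ± 0.05 (SD, n = 2), and an adjusted p of 0.963. Clones of SOD2 on part B gave a mean of 0.05, with 0.36 on replicate 1 and -0.26 on replicate 3.

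Genes of the p53 target list were above 0 for 10 of 14 members on part A, with a median log2 ratio of 0.26 (adjusted p = 0.723), and for 10 of 10 on part B, also with a median of 0.26 (adjusted p = 0.437). These counts use means of 2 arrays, and several members on part B changed sign between the arrays. BCL6 gave -0.42 on replicate 1 and 1.04 on replicate 3, and SERTAD1 gave 1.03 and -0.54. The parts also share members, CDKN1A among them, so they are not separate sets of genes. The members of the p53 list with the largest moderated statistic were MXD4 and RRM2B, both on part A. MXD4, a partner of MAX, stood at -0.64 ± 0.21, and its 2 clones gave -1.10 and -0.19. RRM2B, a p53-induced subunit of ribonucleotide reductase, stood at 0.42 ± 0.14. The G2/M and mitosis list had 4 of 5 members above 0 on part A, with a median of 0.40 (adjusted p = 0.212) and CDCA3 at 0.59 ± 0.05. This list passed with replicate 2 added at its deposited sign (adjusted p = 0.012), and had an adjusted p of 0.955 with the sign turned, in a range of 0.012 to 0.965 over its alternatives. On part B, 4 of its 8 members were above 0 and 4 below, with the spindle protein NUSAP1 at -1.12 ± 0.85 and an adjusted p of 0.98.

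**Figure D3:**
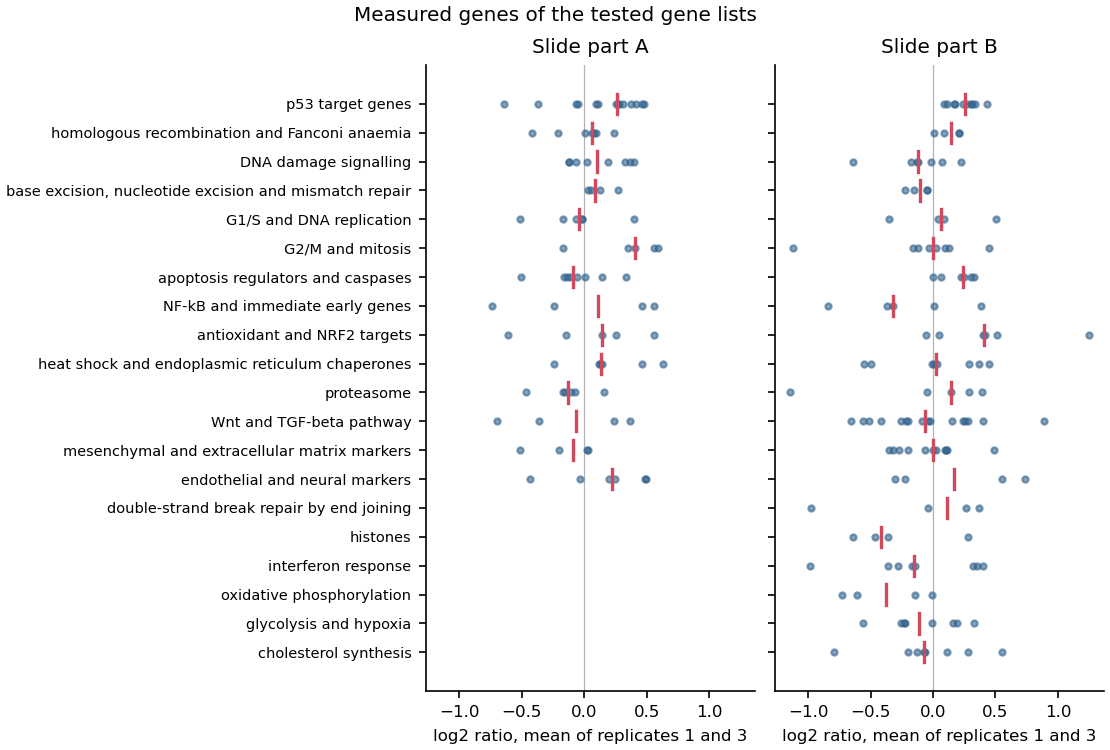
Mean log2 ratio of replicates 1 and 3 for each measured gene (points) and the median (red lines) of every gene list with at least 4 measured genes, on slide part A (left) and slide part B (right). The medians of the p53 target list are 0.26 on both parts, and points of most other lists lie on both sides of 0.

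The other 28 tests gave adjusted p between 0.68 and 0.98. Among lists of DNA repair, the end joining list had 2 of 4 members above 0 on part B, with DNA ligase gene LIG3 at -0.98 ± 0.32, and on part A the damage mediator TP53BP1 gave -0.74 ± 0.17. The homologous recombination and Fanconi anaemia list had 5 of 7 members above 0 on part A and 4 of 4 on part B, with nuclease MRE11 at -0.42 ± 0.53 and RAD51B at 0.24 ± 0.15 on part A. The list of excision and mismatch repair was above 0 for 4 of 4 members on part A and for 0 of 4 on part B, with damage sensor DDB2 at 0.27 ± 0.18 on part A and CETN2 at -0.22 ± 0.01 on part B. DNA damage signalling had 5 of 8 members above 0 on part A and 2 of 7 on part B, with checkpoint kinase CHEK1 at 0.40 ± 0.13 on part A and the histone H2AX at -0.64 ± 0.61 on part B. With a local trend removed these were 0.36 for CHEK1 and -0.11 for H2AX. The G1/S and DNA replication list had 1 of 6 members above 0 on part A and 3 of 4 on part B, and its origin recognition subunit ORC3 stood at -0.52 ± 0.28 and its helicase subunit MCM6 at 0.40 ± 0.05 on part A. Histones were above 0 for 1 of 4 members on part B, with H2BC21 at -0.47 ± 0.06. Apoptosis regulators had 3 of 8 members above 0 on part A and 5 of 6 on part B, with BNIP3 at -0.50 ± 0.16 and AIFM1 at 0.34 ± 0.22 on part A. Both were smaller with a local trend removed, BNIP3 at -0.13 and AIFM1 at 0.17.

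Among stress and signalling lists, heat shock and endoplasmic reticulum chaperones had 5 of 6 members above 0 on part A and 5 of 8 on part B. The constitutive chaperone HSPA8 gave 0.63 ± 0.08 and DNAJC3 gave 0.47 ± 0.01 on part A, and DNAJC3 gave -0.02 there with replicate 2 added at its deposited sign. With the local trend removed from replicates 1 and 3 the values were 0.78 for HSPA8 and 0.04 for DNAJC3. On part B clones of DNAJC3 gave 0.03. NF-kB and immediate early genes had 2 of 4 members above 0 on part A and 2 of 5 on part B, with EGR3 at -0.74 ± 0.36 on part A and the phosphatase DUSP1 at -0.84 ± 0.62 on part B. The interferon list had 3 of 8 members above 0 on part B, where IFI16 gave -0.99 ± 1.36, and IFI44L gave 0.54 ± 0.48 on part A. The Wnt and TGF-beta list had 2 of 4 members above 0 on part A and 6 of 16 on part B, with the Wnt antagonist DKK1 at 0.89 ± 0.02 on part B and the receptor TGFBR1 at -0.70 ± 0.60 on part A.

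Among metabolic lists, oxidative phosphorylation had 0 of 4 members above 0 on part B, with a median of -0.38, and its complex I genes NDUFV1 on part B and NDUFB2 on part A gave -0.61 ± 0.10 and -0.59 ± 0.39. The proteasome list had 1 of 6 members above 0 on part A and 3 of 5 on part B. Its assembly factor gene PSMD5 gave -1.15 ± 0.31 on part B and was the 1 member that passed when adjusted over the list alone, and PSMD11 gave -0.46 ± 0.24 on part A. Glycolysis and hypoxia genes and cholesterol synthesis genes each had 3 of 8 members above 0 on part B, where PFKFB3 gave -0.56 ± 0.70 and IDI1 gave -0.79 ± 0.75, and FADS2 gave 0.50 ± 0.01 on part A. The ribosomal protein genes RPS3 and RPL41 gave -1.0 ± 0.35 and -0.74 ± 0.69 on part B, where the 2 clones of RPL41 gave -0.98 and -0.31. In the metallothionein list, the metal-responsive factor MTF1 gave -0.80 ± 0.63 on part B. The metallothionein MT1F gave 0.03 ± 0.19 on part A and -0.0033 with arrays centred again. These lists, that of colon epithelium and that of blood cells had too few measured genes for a test on either part.

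Markers of other cell types were examined as well. A ratio between 2 cultures gives no level, and a contamination common to both would not show, so purity was not measured. Mesenchymal and matrix markers were above 0 for 2 of 4 genes on part A and 5 of 11 on part B, with COL4A1 at -0.51 ± 0.15 on part A and CDH2 at 0.49 ± 0.01 on part B. Endothelial and neural markers were above 0 for 4 of 6 genes on part A and 2 of 4 on part B, with PECAM1 at 0.74 ± 0.10 on part B and FLT1 at 0.49 ± 0.05 on part A. The B cell gene CD79B gave 0.01 ± 0.25 on part A, and -0.02 with arrays centred again on their medians. Of colon epithelium genes, CEACAM6 gave -0.72 ± 0.80 on part B and FABP1 gave -0.72 ± 1.09 on part A. Of 67 values of named genes and slide parts, 24 changed sign in at least 1 alternative setting. In 5 of the 34 tests the median of the list and the direction of the test, which is relative to the other genes, differed in sign. These were homologous recombination and NF-kB genes on part A, and end joining, proteasome and mesenchymal genes on part B. In simulated lists of 10 genes the test found a common shift of 0.25 log2 units at an unadjusted p under 0.05 in 78% of runs on part A and 62.5% on part B. Most of the 34 tests held fewer genes and all were adjusted, and the simulated genes were independent. The real tests could therefore find less than these shares.

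Genes with clones on both slide parts allowed a comparison that shares no slide. For 520 genes measured on all arrays of both parts, the mean log2 ratios of part A and part B had a Pearson correlation of 0.0081 across genes (permutation test, two-sided, p = 0.854) and a Spearman correlation of 0.0227 (p = 0.606). The 95% interval of the Pearson correlation ran from -0.0779 to 0.0940. Of the 520 genes, 265 had the same sign on both parts. CDKN1A was above 0 on both by its means. On part B its replicate 3 gave -0.06, and its mean with the local trend removed was -0.045. RECK, DUSP1, FLT1, TP53BP1 and COL4A1 had one sign on replicates 1 and 3 of part A and the other on those of part B, RECK with means of -2.25 on part B and 0.34 on part A. By their means alone, LRATD2, PECAM1 and RPL41 also had opposite signs. Within a part, pairs of different clones of one gene gave Pearson correlations of 0.0698 over 328 pairs on part A and 0.0556 over 287 pairs on part B, with Spearman correlations of 0.101 and 0.108. One clone spotted at separate places gave Pearson correlations of 0.0361 over 99 pairs on part A and 0.0343 over 253 pairs on part B. Their 95% intervals ended at 0.232 and 0.157. The reliability of the mean of replicates 1 and 3, taken from their correlation, was higher, at 0.428 and 0.306. Values of a clone thus repeated between arrays at one place but not clearly at another place, which limits every value given for a named gene. The Pearson correlations of these 5 relations formed one family, and each had an adjusted p of 0.854 (permutation tests, two-sided, Benjamini-Hochberg). A scan of all constant displacements of the spot numbers against the gene annotation used another measure. It averaged the correlations of repeated clones on the 3 single arrays, replicate 2 included. At the listed position it was 0.148 on part A, the 99.3 percentile of all displacements, and 0.0196 on part B, the 47.8 percentile. Genes are not independent replicates.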

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

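All tests of explanations in this part were chosen after the results were seen. Replicate 2 entered none of the main tests and holds large ratios of its own. On part A, 307 of 3357 genes were at least 2-fold apart between its channels, against 94 on replicate 1 and 139 on replicate 3. On part B the number was 226 of 3257 genes, against 123 on replicate 1 and 239 on replicate 3.

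These ratios did not clearly follow those of replicates 1 and 3 in either sign; no biological explanation was tested, since the labels name the same cells and treatment on all replicates. Spot noise as the whole cause is argued against, since from the agreement of duplicate spots a correlation of 0.267 or more in size was expected with the mean of replicates 1 and 3, and the largest in size was 0.104, with a negative sign on part B. A local trend across the slides is argued against as the whole cause, since after its removal the largest correlation was still only 0.0733 in size. A dye bias of single clones as large as the difference between the RNAs stays open, since absolute ratios correlated (Spearman at least 0.0808) but noise that depends on intensity could give this too. Which dye was the numerator on replicate 2 is not settled, but a turned numerator as the whole cause is argued against, since with its sign turned the largest correlation was 0.104, where the same 0.267 or more was expected. The expected value takes all agreement of replicates 1 and 3, which share a dye assignment, as a difference between the RNAs. With a shared dye bias it would be lower, so a turned numerator or spot noise together with such a bias is not excluded.

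Among genes of the naming rule with clones on both slide parts, 5 had one sign on both fitted arrays of part A and the other on those of part B. Part A minus part B was 2.59 log2 units for RECK, 1.40 for DUSP1 (0.56 and -0.84), 0.79 for FLT1, -1.002 for TP53BP1 and -0.62 for COL4A1. The difference between the parts was tested over the 520 shared genes, where 0 passed an adjusted p of 0.05 (limma, two-sided) and 57 had an unadjusted p under 0.05. Each of the 5 genes had an adjusted p of 0.419. When arrays of the same replicate number were paired, RECK (adjusted p = 1.2e-06, limma) and DUSP1 (0.047) passed. That fit gave 1 common spread to all genes, and the labels do not show that these arrays are pairs.

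More generally, clones of one gene moved together weakly at most; no biological explanation was tested. Spot noise as the whole cause is argued against, since the Pearson correlation between clones of a gene was at most 0.0698 while the mean of replicates 1 and 3 had a reliability of at least 0.306. A local trend is argued against as the whole cause, since after its removal the correlation was at most 0.0910, against a reliability of at least 0.351, although the Spearman correlation on part A was then 0.126 (permutation test, two-sided, p = 0.0223, not adjusted). The reliability was taken over all spot pairs, named or not, of replicates 1 and 3, which share a dye assignment and spot positions. With a shared bias of spots it would be lower, so noise or a trend together with such a bias is not excluded. A constant displacement of spot numbers against the annotation stays open. The scan averaged the correlations of repeated clones on the 3 single arrays, replicate 2 included. In the scan the listed position stood at the 99.3 percentile of all displacements on part A and at the 47.8 percentile on part B. If spot numbers were displaced, the gene names of that part would be wrong.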

How the results depend on the processing

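The alternatives that remove a local trend, test named genes only or average unnamed neighbouring spots, and the test of the difference between the parts, were chosen after seeing the data. The count of features past an adjusted p of 0.05 was 0 on both parts in all 16 limma settings, with a lowest adjusted p of 0.0787 on part A (dye term, replicate 2 turned) and 0.209 on part B. Genes at least 1.5-fold apart numbered 100 on part A and 116 on part B; they numbered 641 and 658 at 1.2-fold, 7 and 12 at 2-fold, 16 and 20 with replicate 2 at its deposited sign, 17 and 25 with it turned, and 320 and 382 when spots were counted singly. With the local trend removed they numbered 64 and 93, and then 6 and 15 with replicate 2 as deposited and 11 and 12 with it turned. Leaving out 1 replicate gave 100 to 572 on part A and 116 to 685 on part B, because fewer arrays must meet the rule (572 and 685 without replicate 1, 444 and 539 without replicate 3). Of 510 list tests over all settings, 2 passed an adjusted p of 0.05: 1 on part A (G2/M and mitosis, replicate 2 at its deposited sign, 0.012) and 1 on part B (antioxidant and NRF2, estimated correlation, 0.0487). Elsewhere the adjusted p of the antioxidant list reached 0.948 and that of the G2/M list 0.965, and the p53 target list lay between 0.538 and 0.948 on part A and between 0.24 and 0.948 on part B. The G2/M list pointed down on part A with a dye term and replicate 2 turned (0.877) and with the trend removed and replicate 2 turned (0.965). The Pearson correlation between parts was -0.0324 with replicate 2 turned and -0.0427 with a dye term as well; without a replicate it ran from -0.0211 to 0.0081. The Spearman correlation was -0.0250 with a dye term and replicate 2 as deposited, -0.0368 with it turned, and ran from -0.0022 to 0.0553 without a replicate. All of these correlations had a permutation p above 0.05. Of 67 values of named genes, 43 kept their sign in every setting compared and 24 did not. The setting with single spots was not compared in this way. With replicate 2 at its deposited sign, the log2 ratio was -0.016 for DNAJC3, -0.068 for CD79B, 0.036 for TP53BP1, 0.12 for ATM and 0.17 for CETN2; with it turned, -0.020 for CDKN1A on part A and -0.21 for MT1F. With a dye term and the deposited sign it was -0.057 for FLT1, -0.11 for DDB2, -0.11 for CD79B, -0.18 for CHEK1, -0.26 for DNAJC3, -0.27 for IFI44L, 0.0050 for PSMD11, 0.017 for NDUFV1, 0.041 for COL4A1, 0.070 for MRE11, 0.27 for ATM, 0.37 for CETN2 and 0.42 for TP53BP1. With a dye term and the turned sign it was -0.054 for AIFM1, -0.12 for CDCA3, -0.19 for CDKN1A on part A, -0.33 for MT1F, 0.027 for FABP1, 0.067 for PFKFB3, 0.24 for BNIP3, 0.36 for EGR3 and 0.47 for OTX2. Median centring gave -0.0033 for MT1F and -0.018 for CD79B. Removal of the trend gave -0.0054 for MT1F, -0.015 for CD79B and -0.045 for CDKN1A on part B; with replicate 2 as deposited as well, -0.22 for DNAJC3, -0.25 for IFI44L, 0.010 for TP53BP1, 0.027 for PSMD11, 0.063 for H2AX, 0.080 for CETN2 and 0.23 for ATM; with it turned, -0.024 for CD79B, -0.062 for AIFM1, -0.18 for CDKN1A on part B and -0.22 for MT1F. Leaving out 1 replicate gave -0.061 to 0.24 for CDKN1A on part B, -0.11 to 0.16 for MT1F, -0.17 to 0.19 for CD79B, -0.56 to 0.21 for ATM and -1.49 to 0.052 for FABP1. The cause of these changes was not tested. With 1 array left there are no residual degrees of freedom, so gene and list tests without replicate 1 or 3 had no value, and leaving out replicate 2 is the reported fit. Array weights were not run. Replicate numbers can pair arrays only across the slide parts, for the 520 shared genes. The difference between the parts passed for 0 of them without a replicate block and in the 5 other settings run without one, and for 13 with a replicate block, 10 higher on part A and 3 lower, among them RECK and DUSP1. The block fit gave 1 common spread to all genes, and replicate 1 minus replicate 3 correlated at -0.0618 between the parts. This cannot tell whether arrays of one number share RNA or a day, since the ratios of a gene on the parts did not clearly correlate either, and the labels give the arrays only a shared number. Signal over background was not available per spot, so no limit from it can be stated.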

Other observations

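All tests and percentiles in this part were chosen after the results were seen, for 3 of 24 lists, those with an unadjusted p under 0.05 on a slide part. The median of the p53 target list lay above that of all genes of its slide part on replicates 1 and 3, though 4 of 14 members on part A were below 0. It stood at the 99.1 percentile of 10000 random lists of the same size on part A and at the 98.0 percentile on part B. The list was picked for its values on these arrays, so this is a description of them and no independent test. In the list test its unadjusted p was 0.204 on part A and 0.0385 on part B (cameraPR). That test uses the moderated statistic of every member, while the percentile rests on the median alone. On part A a local trend across the slides is argued against as the whole cause. After its removal the median there was 0.25, at the 99.45 percentile with 10 of 14 members above 0. On part B the median was then 0.26, at the 97.54 percentile with 8 of 10 members above 0. This exceeded the stricter bound for excluding the trend by less than its sampling error of 0.304, so the trend was not excluded on part B. The bounds were set after the results were seen. A p53 response in irradiated CloneK cells is a hypothesis on which replicate 2 decided nothing in either sign: as deposited, 5 of 14 members were above 0 on part A and 2 of 10 on part B, at percentiles of 32.3 and 30.6, and with the sign turned 9 of 14 and 8 of 10, at 67.7 and 69.4. With the trend removed the percentiles of replicate 2 were 68.9 (8 of 14 members above 0) and 33.3 (4 of 10) as deposited, and 31.1 (6 of 14) and 66.7 (6 of 10) with the sign turned. The hypothesis stays open, since replicate 2 did not clearly follow the other arrays and a standing difference between the clones would give the same values; in the list test the adjusted p stayed above 0.05 in all settings.

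Genes of the antioxidant and NRF2 list on part B gave the highest percentile of the 3 lists examined this way, 99.9 on replicates 1 and 3 and 99.7 with the local trend removed. On replicate 2, whose sign is not settled, it stood at 27.1 as deposited and 72.9 with the sign turned, and at 17.0 and 83.0 with the trend removed. On part A the same list stood at the 75.7 percentile on replicates 1 and 3, and at 63.3 with the trend removed. The G2/M and mitosis list on part A was at the 98.9 percentile on replicates 1 and 3, with a median of 0.40, but at 91.4 with a median of 0.23 after removal of the trend. On replicate 2 it stood at the 99.2 percentile as deposited but at 0.77 with the sign turned, and at 99.3 and 0.70 with the trend removed, so whether that array goes with the others rests on its unsettled sign. On part B its percentile on replicates 1 and 3 was 42.5, and 42.9 with the trend removed, and on replicate 2 it was 28.8 as deposited and 71.2 turned, and 37.7 and 62.3 with the trend removed.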
